A study of Mus musculus with 16 samples.

How the data were processed

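Poly(A) RNA of colon from C57BL/6J mice was measured by RNA sequencing in 16 libraries, made with the TruSeq stranded mRNA kit per the labels. The labels place the libraries in 4 groups of 4, by diet (lean, 10% of energy from fat, or obese, 60%) and by fiber (cellulose as the control or oligofructose, a fermentable prebiotic fiber, each at 10% by weight). The diets began at 5 weeks of age and the fibers at 17 weeks. The labels do not say that each library came from a separate animal, how animals were caged or which part of the colon was taken. Replicate numbers follow the order of the submission and pair no libraries.

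The deposited files hold raw read counts per gene symbol, 1 file per library, with no normalization and with 5 summary lines of HTSeq that are no genes. The submitters' notes name Trimmomatic 0.32, STAR 2.4.2a, HTSeq 0.6.1 and DESeq2 and the builds mm10 and GRCm38.p4, without giving the role of each. The annotation release and the strand setting used for counting are not stated in the sources used here. Gene counts per library summed to between 11.8 and 27.9 M. Between 9.77% and 11.8% of uniquely placed reads fell outside annotated genes, 0.886% to 0.968% were ambiguous, and 20.7% to 26.7% of all reads were not uniquely placed. The 10 most abundant genes held 5.73% to 8.59% of counts. In 24 pairs of libraries checked for a library deposited more than once, the counts differed by 6.40 to 68.6 times the sampling variance. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

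Of 45664 symbols, 15887 passed edgeR's filterByExpr by group and were tested. Chromosome, start and end were taken by symbol from GENCODE M21 (GRCm38), where 41852 of all symbols and 15208 of the tested ones matched exactly 1 gene. Counts were scaled by TMM and fitted over all 16 libraries with edgeR 4.0.16 (R 4.3.3, quasi-likelihood, robust) with a term for each group and a term for the set of the library's name, d_colon for 1 library per group and S for the other 3. No label calls these sets batches. The S and d_colon libraries differed at 993 genes, 580 higher and 413 lower in S. All 6 contrasts came from this fit, with Benjamini-Hochberg adjustment over the tested genes within each contrast and a threshold of 0.05. Levels are CPM, gene counts scaled by the TMM-adjusted library total, as mean ± SD over 4 libraries. Fold changes are on the log2 scale. Their standard error (SE) was derived as the size of the log2 fold change over the square root of its quasi-likelihood F. Every adjusted p of a gene is from edgeR, unless another tool is named, and is two-sided.

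A total of 38 gene lists were fixed, covering pathways of the colon and markers of the cell types that a piece of colon can hold, and the 36 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Each list test was repeated with the correlation estimated from the data and with fry, which asks whether a list's genes move on balance in 1 direction, or in either direction, without comparing them with other genes. Adjusted p of lists are Benjamini-Hochberg values over the 36 lists. The genes to be named were also set by rule. In each contrast these were the 6 higher and 6 lower changed genes with the largest fold change and average log2 CPM of at least 1, without unnamed gene models, pseudogenes and antigen receptor segments, and then up to 4 changed members of each list in the order of list p, to at most 30 genes. Where fewer than 6 genes changed, the 10 with the smallest p were named. A fixed panel of genes was allowed in each contrast, which included Muc2, Tjp1, Ocln, Reg3b, Reg3g, Tnf, Il1b, Ccl2, Adgre1, Pdk4 and Slc5a8. Groups, contrasts, lists, this rule and the other settings tried were chosen before the data were examined.

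The other settings were DESeq2's size factors and upper quartile factors in edgeR, no filter beyond 1 count, a filter of CPM above 1 in at least 4 libraries, no robust step, no term for the name set, the S libraries alone, only the libraries of the groups compared, the mean level of the smooth muscle list as a covariate, DESeq2 1.42.0, limma voom with quality weights, and each library of the compared groups left out in turn. After the data were seen, further alternatives were added: the mean log2 CPM of Hoxd10 to Hoxd13 as a covariate, the fit without the 4 libraries in which that mean was below 3, and contrasts averaged over the other factor. The fit was tested on simulated data with the same libraries, where 47.8% to 59.7% of genes given a 1.5-fold change were recovered in the contrasts of groups and 25.4% in the contrast of the fiber effects, against 95.5% to 97.0% and 92.4% at 4-fold. These simulated contrasts called 120 to 172 genes each, more than most real ones, so recovery in contrasts with few calls is likely lower. False calls ranged from 3 of 149 to 13 of 172 in the contrasts of groups, and were 4 of 120 in the contrast of the fiber effects. The genes were simulated independently of each other. All libraries were kept, and no other kind of data was analysed here.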

Results

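Colon mRNA was profiled in lean and obese mice given cellulose or oligofructose, with 4 libraries in each of the 4 groups. Gene counts were 21.5, 16.5, 17.6 and 14.8 M in lean cellulose replicates 1 to 4, and 27.9, 15.5, 15.8 and 15.1 M in the lean oligofructose replicates. The obese cellulose replicates held 22.9, 15.6, 15.4 and 11.8 M, and the obese oligofructose replicates 20.5, 15.3, 14.9 and 15 M. Replicate 1 of each group belongs to the d_colon name set and the others to the S set. The study's title concerns the gut microbiome and the osteoarthritis of obesity. The comparisons below ask how the colon transcriptome differed with the obese diet, with oligofructose, and with oligofructose on each diet.

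Hoxd10, Hoxd11, Hoxd12 and Hoxd13, patterning genes of the posterior body and hindgut, differed widely between libraries of the same group. Their mean log2 CPM was 0.28 in lean cellulose replicate 3, 1.65 in lean oligofructose replicate 1, 1.35 in obese oligofructose replicate 1 and 1.77 in obese oligofructose replicate 3. In the other 12 libraries it lay between 3.88 and 5.13. Hoxd13 (chromosome 2, 74668310 to 74671599) was at 91.3 ± 63.9 CPM in lean cellulose, 75.5 ± 42.9 in lean oligofructose, 102 ± 29.2 in obese cellulose and 54.3 ± 47.8 in obese oligofructose (SD, n = 4). The first principal component held 27.5% of the variance and placed the same 4 libraries at -51.1 to -31.5, against 2.78 to 24.9 for the others. None of the low libraries was in obese cellulose. The count of each comparison is therefore also given without these 4 libraries, an alternative chosen after the data were seen.

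**Figure D1:**
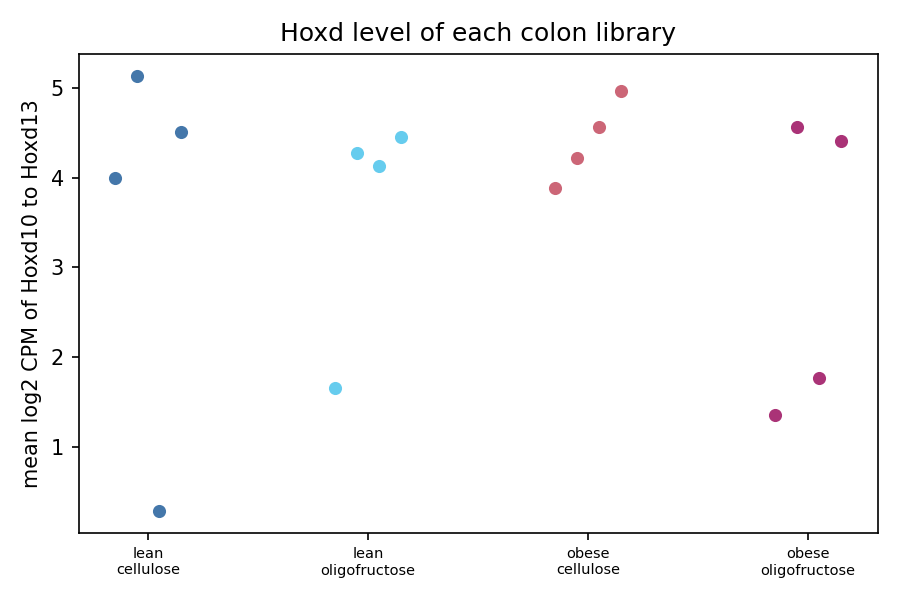
Mean log2 CPM of Hoxd10 to Hoxd13 in each of the 16 libraries, by group, with 1 point per library. The 4 libraries between 0.28 and 1.77 lie apart from the 12 between 3.88 and 5.13, and obese cellulose has none of them.

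Obese against lean mice on cellulose showed higher Arg2, Creb3l3, Angptl4 and Lama3 and lower Hmga1 and Fgfbp1. Arg2, the mitochondrial arginase (chromosome 12, 79130777 to 79156301), rose from 1.60 ± 0.301 to 5.08 ± 1.32 CPM (SD, n = 4), a log2 fold change of 1.67 (SE 0.237, adjusted p = 0.0182). Creb3l3, a transcription factor of lipid metabolism (chromosome 10, 81084324 to 81098874), rose from 3.43 ± 0.934 to 16.4 ± 4.50 CPM (log2 fold change 2.28, SE 0.361, adjusted p = 0.0327). Angptl4, a secreted inhibitor of lipoprotein lipase (chromosome 17, 33773750 to 33781830), rose from 1.79 ± 0.667 to 11.6 ± 9.80 CPM (2.44, SE 0.41, adjusted p = 0.0395). Lama3, a laminin chain of the basement membrane (chromosome 18, 12333819 to 12583013), rose from 115 ± 17.9 to 255 ± 24.7 CPM (1.13, SE 0.165, adjusted p = 0.0213). Angptl4 was at 25.9, 9.4, 6.95 and 4.1 CPM in obese cellulose replicates 1 to 4, in the same order as the adipocyte gene Adipoq at 38.6, 13.1, 3.31 and 1.93. In lean cellulose replicates 1 to 4 Angptl4 was at 2.18, 2.24, 1.92 and 0.81 CPM beside Adipoq at 16.9, 16.8, 12.3 and 2.43. The adipocyte list, with a median log2 fold change of 0.05 between these groups (-0.199 to 0.211 with 1 library left out), was not called (camera adjusted p = 0.547). For each of these 4 genes, every obese cellulose library lay above every lean cellulose library.

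Hmox1, which encodes heme oxygenase, and Ahnak2 also rose, by 1.06 (SE 0.178) and 0.82 (SE 0.134) on the log2 scale. Hmga1, a chromatin architecture protein (chromosome 17, 27556497 to 27563674), fell by 0.55 (SE 0.0866), from 28.7 ± 3.36 to 19.7 ± 3.15 CPM, and Fgfbp1, a carrier of fibroblast growth factors, fell by 0.81 (SE 0.143). In all, 19 of 15887 genes changed, 15 higher and 4 lower, and 2247 had an unadjusted p under 0.05. The smooth muscle covariate left 4, of which 2 were among the 19, and the S libraries alone left 9, of which 6 were. The count was 31 without a filter, 153 with the Hoxd covariate and 844 without the 4 low-Hoxd libraries. DESeq2 called 319 and limma voom with quality weights 991. Every library moved the count by over 1.5 times: it was 12, 5, 59 and 3 without lean cellulose replicates 1 to 4, and 1, 10, 0 and 11 without obese cellulose replicates 1 to 4. Each named gene thus lost its call without obese cellulose replicate 3, where edgeR left 0 genes.

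Of the fatty acid oxidation and ketogenesis list, 2 of 33 tested members rose, Angptl4 and Creb3l3, and 11 were higher and 1 lower when adjusted over the list alone. Acadl, an acyl-CoA dehydrogenase of the mitochondria, was among these, at 135 ± 14.6 and 178 ± 11.7 CPM (log2 fold change 0.40, adjusted p over all genes = 0.0683). The list's median log2 fold change was 0.17 and its camera adjusted p 3e-08. With an estimated correlation the list's adjusted p was 0.241. In the inflammatory cytokine and chemokine list 0 of 21 members passed over all genes and 5 were higher when adjusted over the list alone, with a camera adjusted p of 0.00124 (adjusted p = 0.589 with an estimated correlation). Tnf was at 1.06 ± 0.348 and 2.24 ± 0.644 CPM (1.09, SE 0.32, adjusted p = 0.164) and did not pass. Lists of immune cells moved in the same direction, with medians of 0.30 for MHC class II antigen presentation (camera adjusted p = 0.00123), 0.23 for macrophages (0.00179), 0.40 for T and natural killer cells (0.0024) and 0.64 for B and plasma cells (0.0184). None of their members passed by edgeR, also when adjusted over each list alone, and with an estimated correlation the adjusted p was 0.643 or more for each. The macrophage list lost its call without lean cellulose replicate 3 (0.172) or obese cellulose replicate 1 (0.116), as did the T and natural killer cell list (0.0526 and 0.107). The B and plasma cell list lost it without any 1 of lean cellulose replicates 1 to 3 (0.0734, 0.0901 and 0.134) or obese cellulose replicates 1 and 2 (0.27 and 0.37). The medians moved by over 1.5 times without obese cellulose replicate 1 for MHC class II (0.158), T and natural killer cells (0.229) and macrophages (0.142), without lean cellulose replicate 3 for macrophages (0.0888) and without obese cellulose replicate 2 for B and plasma cells (0.265). With the smooth muscle covariate the inflammatory (0.15), MHC class II (0.245), macrophage (0.594), T and natural killer cell (0.756) and B and plasma cell (0.939) lists were not called.

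The smooth muscle list had a median of -0.42 and a camera adjusted p of 3.65e-09 (adjusted p = 0.634 with an estimated correlation). The median was -0.27 without lean cellulose replicate 3. None of its 19 members passed over all genes by edgeR and 3 were lower when adjusted over the list alone. The intestinal stem cell list had a median of -0.22, with 0 of 16 members past the threshold and 2 lower when adjusted over the list alone (camera adjusted p = 0.000756, and adjusted p = 0.215 with an estimated correlation). Of the barrier genes in the panel, Muc2, the main mucin of the colon, was at 4709 ± 3080 and 3343 ± 117 CPM (adjusted p = 0.579), and Ocln, a tight junction protein, at 151 ± 20.4 and 164 ± 20.2 CPM (adjusted p = 0.601). In lean cellulose replicates 1 to 4 Muc2 was at 4049, 2606, 9241 and 2942 CPM, highest in replicate 3, of low Hoxd level. Tjp1 had a log2 fold change of 0.35 (SE 0.125, adjusted p = 0.231). None of the 3 passed. In the antimicrobial and epithelial defence list the median was 0.161 and the mean -0.138, with a camera adjusted p of 0.0445 for higher expression (adjusted p = 0.643 with an estimated correlation). That call was lost without lean cellulose replicates 1 or 2 (0.201 and 0.134) or obese cellulose replicates 2 or 3 (0.217 and 0.102). The median was 0.0621, 0.302 and 0.283 without lean cellulose replicates 1, 3 and 4 and 0.272 without obese cellulose replicate 1. At the preset correlation 15 of 36 lists were called, and 0 with an estimated correlation. By fry, which asks whether the list itself moves rather than whether it moves more than other genes, 2 were called in 1 direction and 3 in either.

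Obese against lean mice on oligofructose differed in Nos2, in the cytokine genes Tnf, Cxcl1 and Ccl20, in some genes of the interferon response and of fatty acid oxidation, and in the stem cell marker Lgr5. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), rose from 1.51 ± 0.469 to 15.7 ± 2.89 CPM (SD, n = 4; log2 fold change 3.40, SE 0.254, adjusted p = 1.12e-05). Tnf, the inflammatory cytokine (chromosome 17, 35199381 to 35202007), rose from 1.67 ± 0.699 to 5.82 ± 1.23 CPM (1.80, SE 0.301, adjusted p = 0.0146). Tnfrsf8, which encodes CD30, rose from 1.17 ± 0.367 to 4.6 ± 0.998 CPM (1.98, SE 0.262, adjusted p = 0.00477). The neutrophil chemokine Cxcl1 rose from 0.261 ± 0.195 to 1.88 ± 0.458 CPM (adjusted p = 0.0137) and Ccl20 from 5.98 ± 1.28 to 12.1 ± 3.36 CPM (adjusted p = 0.0477). Cxcl1 was expressed at a low level, with an average log2 CPM of 0.187 and 0.0658 to 0.507 CPM in the lean libraries, which is few counts. For Nos2, Tnf, Tnfrsf8, Cxcl1 and Ccl20 every obese library lay above every lean library. Tnf, Cxcl1 and Ccl20 were the 3 of 21 tested members of the inflammatory cytokine and chemokine list that passed, and 5 were higher and 1 lower when adjusted over the list alone. Il1b and Ccl2 did not pass, with log2 fold changes of 0.07 (SE 0.277) and 0.18 (SE 0.462). The list's median was 0.18 and its camera adjusted p 0.000945, with 0.374 at an estimated correlation, 0.0856 without lean oligofructose replicate 1 and 0.0973 without the 4 low-Hoxd libraries. That median was 0.316 and 0.104 without obese oligofructose replicates 1 and 4. The T and natural killer cell list had a median of 0.42 (camera adjusted p = 0.00338, adjusted p = 0.657 with an estimated correlation), which was 0.711 without obese oligofructose replicate 1. The MHC class II list had one of 0.34 (camera adjusted p = 0.0427, adjusted p = 0.784 with an estimated correlation) and lost its call without lean oligofructose replicates 1 or 2 (0.254 and 0.165) or obese oligofructose replicates 3 or 4 (0.13 and 0.145), while the macrophage list, with a median of -0.04, was not called (camera adjusted p = 0.771). Itgad, an integrin chain of leukocytes, was at 4.43 ± 6.33 CPM against 0.0969 ± 0.0646 (adjusted p = 0.0357). In obese oligofructose replicates 1 to 4 Itgad was at 13.9, 1.79, 1.8 and 0.274 CPM and the adipocyte gene Lep at 58.2, 7.24, 6.38 and 0.479.

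Genes of the interferon response were among those named in this comparison: Zbp1, a sensor of nucleic acids, rose by 1.68 (SE 0.257), Ifit1 by 1.57 (SE 0.295), Rsad2 by 1.29 (SE 0.244) and Rtp4 by 1.06 (SE 0.231) on the log2 scale. They were the 4 of 36 tested members of the list that passed, and 14 were higher when adjusted over the list alone (median 0.45, camera adjusted p = 6.49e-14, adjusted p = 0.374 with an estimated correlation). Of the fatty acid oxidation and ketogenesis list 5 of 33 rose, and 17 when adjusted over the list alone. They included Creb3l3 (1.98, SE 0.353), Eci2 (0.46, SE 0.0813), Acadl (0.43, SE 0.0828) and Acaa2 (0.41, SE 0.0915), the last 3 enzymes of mitochondrial fatty acid breakdown. The list's median was 0.26 (camera adjusted p = 1.52e-13), and its adjusted p with an estimated correlation was 0.0367, or 0.26 without the 4 low-Hoxd libraries. Apob, the apolipoprotein of chylomicrons, rose from 257 ± 35 to 376 ± 64.6 CPM. Dgat2, an enzyme of triglyceride synthesis, rose from 36.7 ± 11.6 to 89.5 ± 41.9 CPM, and was at 150, 62.1, 84.1 and 61.4 CPM in obese oligofructose replicates 1 to 4, in the same order as Adipoq at 55.8, 4.85, 7.42 and 1.23. Elovl5, a fatty acid elongase, fell by 0.43 on the log2 scale.

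Of the antimicrobial and epithelial defence list 2 of 22 rose, Nos2 and the acute phase gene Saa1 (1669 ± 202 to 2365 ± 209 CPM, adjusted p = 0.0437). Adjusted over the list alone, 10 were higher and 1 lower. The median was 0.95, or 0.56 without obese oligofructose replicate 3, and the camera adjusted p 7.48e-13, with an adjusted p of 0.0291 with an estimated correlation, or 0.0736 without the 4 low-Hoxd libraries. Lgr5, the marker of intestinal stem cells (chromosome 10, 115450311 to 115587780), fell from 12.9 ± 3.23 to 6.33 ± 2.20 CPM (log2 fold change -1.03, SE 0.234, adjusted p = 0.0486). The highest obese library, at 9.5 CPM of Lgr5, lay above the lowest lean one, at 8.42. Lgr5 was the 1 of 16 stem cell members that passed, and 9 were lower when adjusted over the list alone. That list's median was -0.38, its camera adjusted p 6.84e-06, and its adjusted p with an estimated correlation 0.0291, or 0.369 without the 4 low-Hoxd libraries. Tppp, which encodes a tubulin-binding protein, fell from 205 ± 37.2 to 89.7 ± 7.65 CPM (adjusted p = 0.0015). Ankrd37 rose, and Zfp7, Kif21b, Lonrf3, Tmem194 and the glucose-regulated Txnip fell. Tmem194 has no position in the annotation used.

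In all, 168 genes changed between obese and lean mice on oligofructose, 98 higher and 70 lower, and 2578 had an unadjusted p under 0.05. The count was 688 with DESeq2, 574 with limma voom, 63 without the name set term, 58 with only the compared groups, 610 with the Hoxd covariate and 1000 without the 4 low-Hoxd libraries. It was 363, 19 and 26 without lean oligofructose replicates 1, 2 and 3, and 31 and 28 without obese oligofructose replicates 3 and 4. The calls for Nos2, Tnfrsf8, Tppp, Zfp7, Zbp1 and Cxcl1 stood without any 1 library. Each of the other genes named was lost without at least 1 library, and adjusted p over all alternatives reached 0.193 for Lgr5 and 0.0665 for Tnf. In the 8 fits without 1 library, Lgr5, Ccl20, Saa1, Dgat2 and Txnip kept their calls in only 1. Acaa2, Rtp4 and Tmem194 kept theirs in 2, and the remaining genes in 3 to 5. At the preset correlation 13 of 36 lists were called, and 3 with an estimated correlation. The heat shock list, called at the preset correlation without any 1 library as well, had a median of -0.62, or -0.336 without lean oligofructose replicate 1, with 0 of 16 members past the threshold by edgeR (camera adjusted p = 5.11e-05, adjusted p = 0.577 with an estimated correlation).

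The diet comparisons within each fiber share no libraries, so their directions could be compared. Of the 19 genes changed on cellulose, 17 had the same sign on oligofructose, and of the 168 changed on oligofructose, 159 had the same sign on cellulose. Arg2, Creb3l3, Lamb3 and Slurp1 rose and Hmga1 fell in both. Chance would give 0.0925 genes higher and 0.0176 lower in both if the calls were independent. Both comparisons come from the same fit and share each gene's variance estimate, so the overlap by chance may be larger. Over all 15887 genes the log2 fold changes of both comparisons had a Pearson r of 0.116 and a Spearman rho of 0.184. Lamb3, another chain of the same laminin as Lama3, and Slurp1, a secreted epithelial protein, were named after their values were seen. Lamb3 was at 180 ± 6.96 and 308 ± 16.8 CPM on cellulose and at 206 ± 43.6 and 286 ± 17.8 CPM on oligofructose, lean and obese (SD, n = 4).

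**Figure D2:**
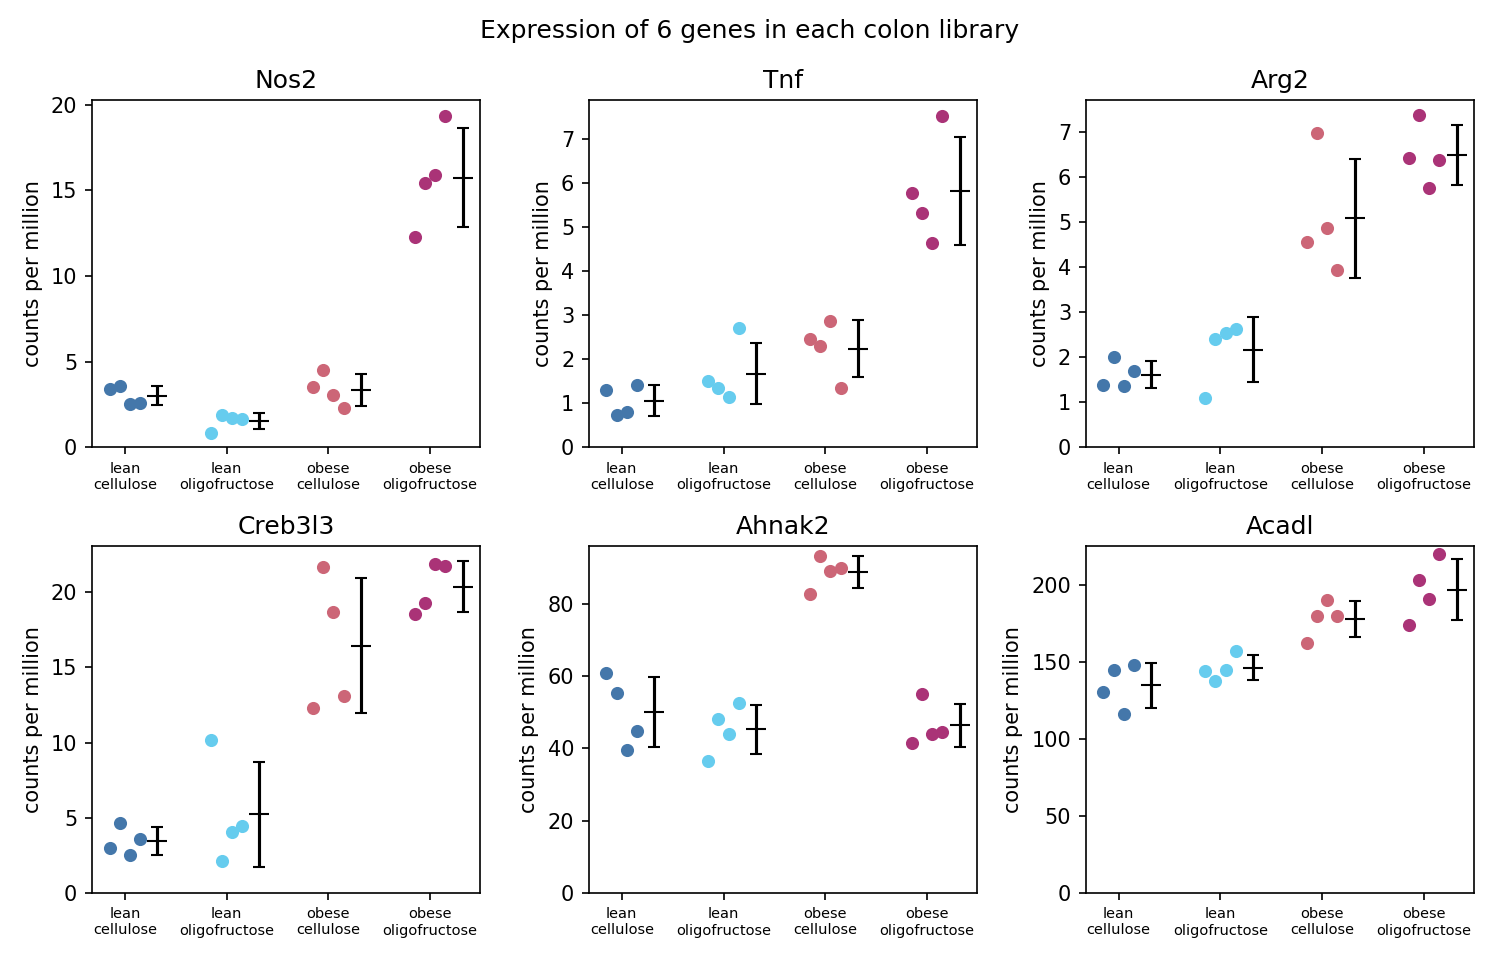
CPM of Nos2, Tnf, Arg2, Creb3l3, Ahnak2 and Acadl in each library, 4 points per group, with the group mean and SD beside them. Nos2 lies at 12.2 to 19.3 CPM in obese oligofructose and at no more than 4.48 CPM in the other groups.

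In obese mice, oligofructose against cellulose was accompanied by higher Nos2 and lower Ahnak2. Nos2 rose from 3.33 ± 0.927 to 15.7 ± 2.89 CPM (SD, n = 4; log2 fold change 2.21, SE 0.236, adjusted p = 0.00155), and the lowest oligofructose library, at 12.2 CPM, lay above the highest cellulose library, at 4.48. Ahnak2, a large scaffold protein (chromosome 12, 112772194 to 112802657), fell from 88.8 ± 4.42 to 46.3 ± 5.98 CPM (-0.94, SE 0.135, adjusted p = 0.0306), beside 50.2 ± 9.68 in lean cellulose. These were the 2 of 15887 genes that changed, and 1929 had an unadjusted p under 0.05. The next smallest p belonged to Ceacam10, a cell adhesion protein (0.78, SE 0.133, adjusted p = 0.155), Tmem189, Cyp2c69 and Zc3h12a, which encodes an RNase that limits cytokine mRNA (27.2 ± 4.19 and 56.6 ± 11.6 CPM, adjusted p = 0.192). None of these passed. Tnf was at 2.24 ± 0.644 and 5.82 ± 1.23 CPM (1.36, SE 0.294, adjusted p = 0.263) and Il1b at 2.23 ± 0.712 and 4.76 ± 1.13 CPM (1.05, SE 0.291, adjusted p = 0.345), and neither passed.

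Of the antimicrobial and epithelial defence list 1 of 22 rose, Nos2, and 8 were higher when adjusted over the list alone (median 0.67, camera adjusted p = 2.98e-10, adjusted p = 0.116 with an estimated correlation, and 0.047 without the 4 low-Hoxd libraries). The median was 0.418 without obese oligofructose replicate 3. Its secreted goblet and crypt cell products varied greatly between libraries. Ang4, an antimicrobial ribonuclease, was at 14.7 ± 10.6 CPM with cellulose and 478 ± 476 with oligofructose, Retnlb at 2.35 ± 2.36 and 275 ± 333, and Itln1, a lectin, at 1.10 ± 0.311 and 17.3 ± 18.4. Replicates 1 and 3 of obese oligofructose, both of low Hoxd level, held the highest values, with Ang4 at 471, 134, 1154 and 155 CPM in replicates 1 to 4, Retnlb at 301, 21.2, 737 and 39.9, and Itln1 at 21.8, 2.46, 41.6 and 3.49. Lean oligofructose replicate 1, also of low Hoxd level, had Ang4 at 530, Retnlb at 229 and Itln1 at 21.6 CPM, while lean cellulose replicate 3, of the lowest Hoxd level, had 68, 9.16 and 2.15. They did not pass over all genes, at an adjusted p of 0.344 for Ang4, Retnlb and Itln1 alike, and were named after their values were seen. Reg3b was at 0.178 ± 0.140 and 1.79 ± 1.59 CPM and Reg3g at 0.823 ± 0.575 and 3.41 ± 1.77 CPM, with adjusted p of 0.355 and 0.384.

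The interferon response list had 0 of 36 members past the threshold by edgeR and 3 higher when adjusted over the list alone (median 0.31, camera adjusted p = 1.12e-07, adjusted p = 0.32 with an estimated correlation), with a median of 0.174 and 0.199 without obese oligofructose replicates 3 and 4. The B and plasma cell list had 0 of 19 past the threshold and 2 higher when adjusted over the list alone (median 0.32, camera adjusted p = 4.76e-07, adjusted p = 0.32 with an estimated correlation). Its median was 0.657, 0.211 and 0.162 without obese cellulose replicates 2 to 4, and 0.485 and 0.152 without obese oligofructose replicates 1 and 3. The T and natural killer cell list had a median of 0.35 (camera adjusted p = 0.0176) and the macrophage list one of -0.17 (camera adjusted p = 0.014), both at an adjusted p of 0.526 with an estimated correlation. The first lost its call without obese cellulose replicate 4 (0.173) or obese oligofructose replicates 2 or 4 (0.159 and 0.0983), and the second without obese cellulose replicate 1 (0.42, median -0.0311). The T and natural killer cell median was 0.56 without obese cellulose replicate 1, and 0.559 and 0.223 without obese oligofructose replicates 1 and 3. Smooth muscle had 0 of 19 past the threshold and 9 higher when adjusted over the list alone, with a median of 0.46 (camera adjusted p = 7.98e-10, adjusted p = 0.32 with an estimated correlation) that became 0.213 without obese oligofructose replicate 1 and 0.03 without the 4 low-Hoxd libraries. Other lists moved as well, with medians of 0.494 for enteric neurons and glia (camera adjusted p = 2.68e-09), 0.599 for tuft cells (3.69e-05) and 0.298 for immediate early genes (3.57e-05). Each had an adjusted p of 0.32 with an estimated correlation. With 1 library left out they kept these calls, at medians of 0.28 to 0.65, 0.373 to 0.826 and 0.21 to 0.455. Such fits do not leave out the low-Hoxd replicates 1 and 3 of obese oligofructose together. In obese oligofructose replicates 1 to 4 the mean log2 CPM for enteric neurons and glia was 4.31, 3.16, 3.87 and 3.36, against 3.12 to 3.31 in obese cellulose. For tuft cells it was 2.81, 2.08, 3.07 and 2.29, against 1.71 to 2.24. For immediate early genes it was 5.94, 5.5, 5.96 and 5.6, against 4.91 to 5.67. Slc5a8, a transporter of short-chain fatty acids, was at 371 ± 35 and 323 ± 80.8 CPM (adjusted p = 0.651). The count of changed genes was 1 with the smooth muscle covariate, where Ahnak2 lost its call (log2 fold change -0.77, SE 0.136, adjusted p = 0.253), 54 with DESeq2, 9 with limma voom and 9 without the 4 low-Hoxd libraries. At the preset correlation 18 of 36 lists were called, with 0 at an estimated correlation. Nos2 kept its call without any 1 library. Ahnak2 lost its call without any 1 of the obese cellulose replicates (adjusted p = 0.131, 0.17, 0.0913 and 0.145 for replicates 1 to 4) and without obese oligofructose replicates 1, 3 and 4 (0.148, 0.221 and 0.229). In the 8 fits without 1 library its log2 fold change lay between -1.03 and -0.90, with an SE of 0.142 to 0.153 against 0.135 with all libraries and an unadjusted p of 3.59e-06 to 3.73e-05 against 3.86e-06.

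In lean mice, oligofructose against cellulose left 1 gene past the threshold, the antibody segment Igkv8-18 (chromosome 6, 70355852 to 70356445), which was lower. It lies outside the naming rule and was named after its values were seen. Igkv8-18 held 185, 129, 55 and 60 counts in lean cellulose replicates 1 to 4 and 1, 0, 1 and 0 in the lean oligofructose replicates. The ratio of lean cellulose to lean oligofructose was 220 (95% counting interval 60.4 to 1820). In the other groups it held 12 counts in obese cellulose replicate 1, 3 in obese oligofructose replicate 4 and 0 in the other libraries. The gene was lost, for a count of 0, without lean oligofructose replicate 1 or 2, with the S libraries alone and without the 4 low-Hoxd libraries. The count was 2 without lean cellulose replicate 2 or lean oligofructose replicate 4, 2 without a filter, 3 with the smooth muscle or the Hoxd covariate, 20 with DESeq2 and 1 with limma voom, and 1063 genes had an unadjusted p under 0.05.

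Among the genes with the smallest p in lean mice, Sult1c2, a sulfotransferase, was at 46.8 ± 8.62 CPM with cellulose and 29.4 ± 1.09 with oligofructose (SD, n = 4; log2 fold change -0.67, SE 0.106, adjusted p = 0.105). Slc5a3, a myo-inositol transporter, was at 64.8 ± 8.98 and 128 ± 42.1 CPM (0.98, SE 0.182, adjusted p = 0.218), and Slc30a10, a manganese exporter, at 8.64 ± 5.86 and 1.89 ± 0.627 CPM (-2.13, SE 0.403, adjusted p = 0.218). Ccng2, Ipmk, Tm4sf20, Snrnp48, Ceacam10 and Piga were higher and Chrac1 lower in the mean, and none passed. The B and plasma cell list had a median of 0.50 with 0 of 19 members past the threshold, also when adjusted over the list alone (camera adjusted p = 6.04e-11, adjusted p = 0.461 with an estimated correlation). Its median was 0.313 without lean cellulose replicate 2. Other lists moved with it. The medians were 0.28 for T and natural killer cells (camera adjusted p = 0.00378), 0.22 for MHC class II antigen presentation (0.00013), 0.27 for proliferation (6.46e-06), -0.19 for fibroblasts and extracellular matrix (0.000459), -0.19 for smooth muscle (0.000737), 0.33 for heat shock (0.000737) and -0.63 for mast cells and eosinophils (0.000597). With an estimated correlation the adjusted p was 0.0743 for mast cells and eosinophils and 0.674 or more for the others. The T and natural killer cell list lost its call without lean cellulose replicate 3 (0.183) or lean oligofructose replicate 4 (0.231), MHC class II without lean oligofructose replicate 4 (0.0542) and proliferation without lean oligofructose replicates 1 or 2 (0.0767 and 0.113). The fibroblast list lost it without lean oligofructose replicate 1 (0.0543) and smooth muscle without lean cellulose replicate 3 (0.576). Heat shock lost it without lean cellulose replicate 1 (0.332) or lean oligofructose replicates 1 or 3 (0.193 and 0.176). With 1 library left out, medians ranged over 0.108 to 0.423 for T and natural killer cells (lowest without lean oligofructose replicate 4) and 0.104 to 0.355 for MHC class II (without lean oligofructose replicate 4 and lean cellulose replicate 4, with 0.137 without lean cellulose replicate 3). The proliferation median was 0.11 without lean oligofructose replicate 2, and the fibroblast median -0.105 and -0.0954 without lean cellulose replicate 2 and lean oligofructose replicate 1. Smooth muscle was at -0.308 and -0.0562 without lean cellulose replicates 1 and 3, and mast cells and eosinophils at -0.384 and -0.976 without lean cellulose replicate 2 and lean oligofructose replicate 4. Heat shock was at 0.0481, 0.776 and 0.212 without lean cellulose replicates 1, 3 and 4, and at 0.0867, 0.144 and 0.568 without lean oligofructose replicates 1, 3 and 4. The interferon response list had a median of -0.19 (camera adjusted p = 0.000111, adjusted p = 0.674 with an estimated correlation), and lost its call without lean cellulose replicate 1 (0.325, median -0.0351) or lean oligofructose replicate 1 (0.0767, median -0.0652). Without lean oligofructose replicate 4 its median was -0.287. At the preset correlation 17 of 36 lists were called, and 9 without lean oligofructose replicate 1. With an estimated correlation the count was 0.

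**Figure D3:**
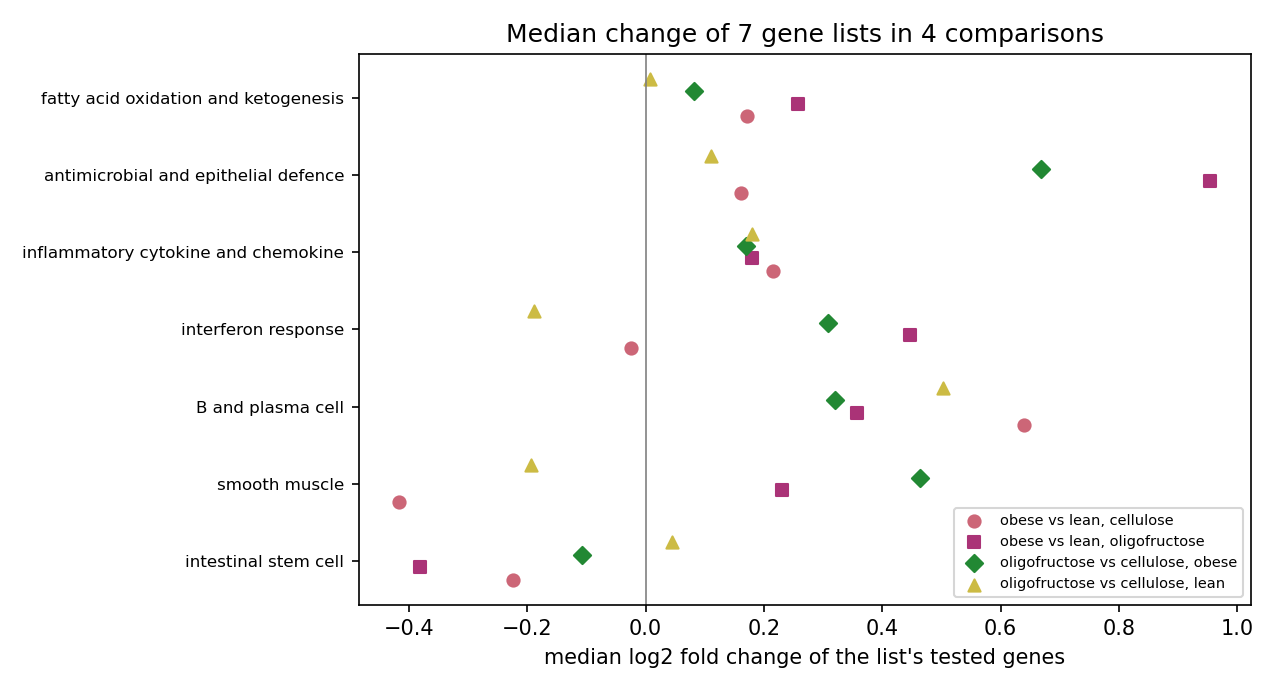
Median log2 fold change of the tested genes of 7 lists in 4 comparisons, with 1 symbol per comparison. The antimicrobial and epithelial defence list lies at 0.95 for obese against lean on oligofructose, or 0.56 without obese oligofructose replicate 3, and at 0.16 for the same contrast on cellulose, or 0.0621 to 0.302 with 1 library left out.

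The effect of oligofructose differed between obese and lean mice for Nos2. Its level went from 3.33 ± 0.927 to 15.7 ± 2.89 CPM in obese mice and from 3.01 ± 0.538 to 1.51 ± 0.469 CPM in lean mice (SD, n = 4), where the change alone did not pass (log2 fold change -1.05, adjusted p = 0.615), and the difference of these effects was 3.26 on the log2 scale (SE 0.346, adjusted p = 0.00145). Nos2 was the 1 gene past the threshold, among 1525 with an unadjusted p under 0.05, and kept its call without any 1 library. Next in p, leaving out antibody segments and unnamed gene models, stood Marveld3, a tight junction protein (-0.59, SE 0.122), Etaa1, Ipmk, Sult1c2, Zbp1, Arid5b, Reg3b, Cenpc1 and Jmjd1c, each with an adjusted p of 0.459, and they did not pass. Reg3b was at 4.21 ± 5.90 and 0.122 ± 0.243 CPM in lean mice and at 0.178 ± 0.140 and 1.79 ± 1.59 CPM in obese mice, on cellulose and oligofructose. The count was 20 with DESeq2, 1 with limma voom, 6 without the 4 low-Hoxd libraries, and 2 without lean oligofructose replicate 1 or obese oligofructose replicate 2.

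The interferon response list had a median difference of 0.54 between the fiber effects, with 0 of 36 members past the threshold by edgeR and 5 higher when adjusted over the list alone (camera adjusted p = 1.08e-11, adjusted p = 0.566 with an estimated correlation). The antimicrobial and epithelial defence list had a median difference of 0.41, with Nos2 past the threshold and 3 of 22 higher when adjusted over the list alone (camera adjusted p = 1.59e-05, adjusted p = 0.476 with an estimated correlation). That median was 0.907 and 0.255 without lean oligofructose replicates 1 and 2, 0.265 without obese cellulose replicate 1 and 0.223 without obese oligofructose replicate 3. For the fatty acid oxidation and ketogenesis list the median difference was 0.09, and the list was not called (camera adjusted p = 0.16). At the preset correlation 11 of 36 lists were called, with 0 at an estimated correlation.

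Obese mice on oligofructose, set against lean mice on cellulose, had higher Nos2, Tnf, Arg2 and fatty acid oxidation genes and lower Axin2 and Cdk6. Tnf rose from 1.06 ± 0.348 to 5.82 ± 1.23 CPM (SD, n = 4; log2 fold change 2.46, SE 0.314, adjusted p = 0.00382). Nos2 rose by 2.35 (SE 0.237, adjusted p = 0.000703), Arg2 by 2.02 (SE 0.236, adjusted p = 0.00247), Creb3l3 by 2.58 (SE 0.363, adjusted p = 0.0104), Angptl4 by 2.43 (SE 0.412, adjusted p = 0.0205) and Tnfrsf8 by 1.69 (SE 0.257, adjusted p = 0.0129) on the log2 scale. Apoc2, an activator of lipoprotein lipase, rose from 4.21 ± 0.398 to 9.39 ± 2.04 CPM, and Slc27a2, a fatty acid transporter, from 4.14 ± 0.641 to 7.69 ± 0.740 CPM. Axin2, a target of Wnt signaling (chromosome 11, 108920349 to 108950783), fell from 46 ± 5.31 to 29.9 ± 3.47 CPM, and the cell cycle kinase Cdk6 from 47.7 ± 4.71 to 34.3 ± 3.18 CPM. Greb1, Tppp, Setd1b and Zfp629 also fell, by 0.54 to 0.97 on the log2 scale.

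Of the fatty acid oxidation and ketogenesis list 4 of 33 rose between lean cellulose and obese oligofructose: Creb3l3, Angptl4, Acadl and Hadha, the last the alpha subunit of the mitochondrial trifunctional protein (268 ± 10.6 to 354 ± 18.4 CPM). Adjusted over the list alone 21 were higher (median 0.31, camera adjusted p = 8.79e-19, adjusted p = 0.0103 with an estimated correlation). Of the antimicrobial and epithelial defence list 2 of 22 rose, Nos2 and Pglyrp1, a peptidoglycan recognition protein, and 16 were higher when adjusted over the list alone (median 0.85, adjusted p = 0.0103 with an estimated correlation). The inflammatory list had 1 of 21 past the threshold, Tnf, and 7 higher and 1 lower when adjusted over the list alone (median 0.47, adjusted p = 0.034 with an estimated correlation). Beside it, the T and natural killer cell list had a median of 0.61, with 3 of 21 higher when adjusted over the list alone (camera adjusted p = 2.66e-09, adjusted p = 0.147 with an estimated correlation), and the MHC class II list one of 0.58, with 8 of 14 (camera adjusted p = 7.52e-09, adjusted p = 0.199 with an estimated correlation). The fibroblast and extracellular matrix list had a median of -0.22, or -0.345 without obese oligofructose replicate 1 (camera adjusted p = 3.49e-06, adjusted p = 0.263 with an estimated correlation), and the macrophage list, with a median of 0.02, was not called (camera adjusted p = 0.471). The T and natural killer cell, MHC class II and fibroblast lists kept these calls at the preset correlation without any 1 library, with 0 members past the threshold over all genes by edgeR. The stem cell list had 1 of 16 lower, Axin2, and 7 when adjusted over the list alone (median -0.35, adjusted p = 0.0103 with an estimated correlation). Without the 4 low-Hoxd libraries the adjusted p with an estimated correlation were 0.181 for fatty acid oxidation, 0.1 for the antimicrobial and inflammatory lists and 0.217 for stem cells. B and plasma cell genes had a median of 0.89 with 0 of 19 past the threshold by edgeR and 16 higher when adjusted over the list alone (camera adjusted p = 5.28e-15, adjusted p = 0.119 with an estimated correlation).

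In all, 55 genes changed between lean cellulose and obese oligofructose, 44 higher and 11 lower, and 2015 had an unadjusted p under 0.05. The count was 299 with DESeq2, 485 with limma voom, 100 with the smooth muscle covariate, 252 with the Hoxd covariate, 10 with only the compared groups and 420 without the 4 low-Hoxd libraries. It was 20, 13, 309 and 17 without lean cellulose replicates 1 to 4, and 87, 17 and 12 without obese oligofructose replicates 1, 3 and 4. Creb3l3, Tnf, Nos2 and Arg2 kept their calls without any 1 library, and each of the other named genes lost its call without at least 1, with adjusted p over all alternatives of up to 0.243 for Pglyrp1. In the 8 fits without 1 library, Axin2 and Apoc2 kept their calls in 2, Cdk6 in 4 and Acadl in 7. At the preset correlation 13 of 36 lists were called. The 4 lists named above with adjusted p of 0.034 or less, and the 3 on oligofructose, were the only ones called in any comparison of groups with an estimated correlation in the fit of all 16 libraries with the name set term and no covariate. Other fits called further lists. In obese mice, oligofructose against cellulose, these were the antimicrobial list without the 4 low-Hoxd libraries (0.047), and with the smooth muscle covariate that list and the T and natural killer cell list (0.0479 each). Between lean cellulose and obese oligofructose it was fatty acid synthesis with the S libraries (0.0449), and for oligofructose in lean mice mast cells and eosinophils without the name set term (0.039).

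The last comparison asks how far the genes changed in obese cellulose stood from the lean level in obese oligofructose. Of the 19 genes, 16 (84.2%) went the opposite way with oligofructose, and the median change from lean cellulose was 0.754 of that in obese cellulose. Ahnak2 was the 1 gene that passed the threshold in the opposite direction, 4 passed when adjusted over these genes alone, and 9 of the 19 still differed from lean cellulose. Both comparisons use the same obese cellulose libraries with opposite sign. With no fiber effect, simulated on the same libraries, the share averaged 73.7% (47.4% to 89.5%), and 10 of 40 simulations reached the observed share. In the same simulations, from values added after the observed ones had been seen and with the 19 genes of smallest p, the median change from lean cellulose averaged 0.878 of that in obese cellulose (0.74 to 1.01), with 1 of 40 as low as 0.754. The genes that passed when adjusted over these genes alone averaged 1.48 (0 to 6), with 5 of 40 at 4 or more. With the obese cellulose libraries split so that different ones defined each change, and the 19 genes of smallest p chosen anew from the first, it averaged 57.9% (31.6% to 84.2% over the splits). The share was 62.3% of 844 genes without the 4 low-Hoxd libraries.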

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

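The tests of Nos2 and the count of antibody segments were chosen only after the results were seen. The tests of leaving out 4 libraries, of shared Igkv8 reads and of splits over all libraries were written down before their values were computed.

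Nos2 rose with oligofructose in obese mice by 2.21 (SE 0.236) on the log2 scale, and the difference between the fiber effects in obese and lean mice was 3.26. With the mean Hoxd level as a covariate the change in obese mice was 2.337 (adjusted p = 0.000209), which argues against position along the colon as the whole cause. Among the lists of 4 kinds of immune cells, the highest median was 0.349, for T and natural killer cells. The highest upper quartile was 0.819, for B and plasma cells. These values argue against more macrophages, T and natural killer cells, B and plasma cells, or mast cells and eosinophils as the whole cause. Neutrophils stay open, since only 3 of the 12 members of their list passed the filter, with a median of 0.112. More cells of a rare kind that makes Nos2, or a higher level in epithelial or immune cells already present, stay open too, since no cell type was measured apart.

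Without the 4 libraries of low Hoxd level, 844 genes changed between obese and lean mice on cellulose, against 19 with all 16. Of 96 choices of 4 libraries with the same number from each group, 1 changed as many, the real one, so an arbitrary choice of 4 libraries does not account for it. The 4 were picked from these data because they lay apart, and they did so on the first principal component too. A high rank among the choices was therefore likely beforehand. Those of the oligofructose groups are not in this comparison and can act only through the shared fit. The highest other choice changed 628 genes and the median other choice 11, so position along the colon could not be told apart from other differences between these libraries. The 24 choices that leave out lean cellulose replicate 3 had a median of 94 apart from the real one, against 6 for the rest. No biological explanation was tested.

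Igkv8-18 was at 3.11 CPM or more in every lean cellulose library and at no more than 0.51 elsewhere. The 6 other tested Igkv8 segments had a median of -0.815 between lean oligofructose and lean cellulose, with a range of -1.63 to 1.73, which leaves shared reads open. Of 196 antibody variable segments, 2 stood apart in 1 group with a floor on the counts, where 0.431 would by chance (exact Poisson test, p = 0.07). Without the floor 3 did (exact Poisson test, p = 0.00968). The floor was chosen after the first count was seen, so whether chance accounts for the segment stays open.

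Dixon's test was applied to log2 CPM with a prior count of 0.5, while the values below are CPM. By chance 1 library lies far from the other 3 in about 1 in 20 groups, or 15 of 300 pairs of a gene and a group. Here 1 library did so in 23 pairs. Of these, 8 were in lean oligofructose replicate 1, with CPM (range of the other 3 in parentheses) of 3.67 for Apoc2 (5.99 to 6.52), 1.09 for Arg2 (2.39 to 2.63), 18.8 for Arid5b (29.2 to 30.7), 54 for Dgat2 (30.1 to 32.5), 35.4 for Eci2 (38.4 to 38.8), 0 for Itgad (0.127 to 0.132), 0.824 for Nos2 (1.65 to 1.87) and 0.487 for Reg3b (0 in each). The Itgad values rest on very few counts. In the other lean oligofructose libraries, Saa1 was at 1970 in replicate 3 (1540 to 1600) and Slc30a10 at 2.83 in replicate 4 (1.54 to 1.61). In lean cellulose, Fbxo25 was at 104 in replicate 2 (91.9 to 92.8), Cxcl1 at 0.226 in replicate 3 (0.49 to 0.544), and Angptl4 at 0.809 (1.92 to 2.24) and Sectm1b at 406 (332 to 336) in replicate 4. In obese cellulose, Ipmk was at 255 (332 to 345) and Tm4sf20 at 226 (305 to 314) in replicate 1, and Cenpc1 at 23.9 in replicate 3 (21.5 to 21.9). In obese oligofructose, replicate 1 had Il1b at 3.09 (5.12 to 5.55), Lonrf3 at 2.16 (3.29 to 3.54) and Marveld3 at 73.7 (95.1 to 99.9). Rsad2 was at 8.7 in replicate 2 (13.1 to 13.7), Kif21b at 71.4 in replicate 3 (58.7 to 60.7) and Pglyrp1 at 235 in replicate 4 (196 to 202).

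The effect of oligofructose differed between obese and lean mice in 11 lists at the preset correlation, and in 0 with an estimated correlation. The median differences were 0.67 for smooth muscle, 0.536 for the interferon response, 0.152 for oxidative phosphorylation, 0.411 for antimicrobial and epithelial defence and 0.421 for enteric neurons and glia. They were 0.314 for cholesterol synthesis, 0.652 for tuft cells, -0.178 for macrophages, 0.179 for xenobiotic metabolism, -0.291 for enteroendocrine cells and -0.435 for heat shock. Without 1 library, the call at the preset correlation was lost in 7 of 16 fits for enteroendocrine cells (median -0.327 to -0.178), in 7 for heat shock (-0.838 to -0.148), in 3 for macrophages (-0.345 to -0.0834) and in 1 for tuft cells, without lean cellulose replicate 3 (camera adjusted p = 0.0726, median 0.209). For enteroendocrine cells these were the fits without lean cellulose replicates 1 and 2 (camera adjusted p = 0.248 and 0.146), lean oligofructose replicates 1 and 2 (0.0992 and 0.0765), obese cellulose replicate 2 (0.0633) and obese oligofructose replicates 2 and 4 (0.241 and 0.0612). For heat shock they were those without lean cellulose replicates 1, 2 and 4 (0.474, 0.105 and 0.12), lean oligofructose replicates 1 and 3 (0.355 and 0.347), obese cellulose replicate 4 (0.116) and obese oligofructose replicate 2 (0.146). For macrophages they were those without lean cellulose replicate 3 (0.117), lean oligofructose replicate 4 (0.0963) and obese cellulose replicate 1 (0.125). The other 7 lists kept their calls without any 1 library. Their medians moved by over 1.5 times for antimicrobial and epithelial defence (0.223 to 0.907), for smooth muscle without obese oligofructose replicate 1 (0.427), and for enteric neurons and glia without lean cellulose replicate 3 or obese oligofructose replicate 1 (0.245 and 0.247). They did so as well for cholesterol synthesis without lean cellulose replicate 3 (0.177) and for xenobiotic metabolism without obese oligofructose replicate 1 (0.118). Fits without 1 library do not leave out the low-Hoxd libraries together. These include obese oligofructose replicates 1 and 3 and lean cellulose replicate 3. The mean log2 CPM for smooth muscle was 9.03, 7.91, 8.5 and 8.24 in obese oligofructose replicates 1 to 4 and 8.25, 8.38, 8.79 and 8.22 in lean cellulose. For enteric neurons and glia it was 4.31, 3.16, 3.87 and 3.36, and 3.56, 3.29, 3.89 and 3.25.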

How the results depend on the processing

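Of 1162 other fits of the 55 calls of named genes, 853 kept the call, 309 lost it and 0 reversed, and 58 of 2156 fits of uncalled genes gained a call. Nos2 kept its call with oligofructose in obese mice (2.05 to 2.41) and between the fiber effects (3.03 to 3.54) in every fit. The cause was not tested for the counts below, except that fits without libraries or with the S libraries hold fewer samples. The library of lowest depth held 11.8 M counts. Depth was not varied, so how it limits genes of low CPM was not tested. In data simulated at the depths of these libraries 73.1% to 83.6% of genes changed 2-fold were recovered in the comparisons of groups and 56.7% in the difference of fiber effects. The genes changed there all had an average log2 CPM above 1. Each simulated comparison of groups called 149 to 172 genes, which loosens the adjusted threshold. Recovery is therefore likely lower in the real comparisons that called few genes. No paired analysis was possible because the labels give no numbers that join libraries between groups.

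Between obese and lean mice on cellulose, 19 genes became 31 without a filter, 9 with the S libraries, 4 with the smooth muscle covariate, 153 with the Hoxd covariate, 844 without the 4 low-Hoxd libraries, 319 with DESeq2 and 991 with limma voom. For oligofructose in obese mice, 2 became 1 with the smooth muscle covariate, 9 without the low-Hoxd libraries, 54 with DESeq2 and 9 with voom. For oligofructose in lean mice, 1 became 2 without a filter, 0 with the S libraries, 3 with the smooth muscle covariate, 3 with the Hoxd covariate, 0 without the low-Hoxd libraries and 20 with DESeq2. Between obese and lean mice on oligofructose, 168 became 63 without the name set term, 610 with the Hoxd covariate, 1000 without the low-Hoxd libraries, 688 with DESeq2, 574 with voom and 58 with only the compared groups. Between obese oligofructose and lean cellulose, 55 became 100 with the smooth muscle covariate, 252 with the Hoxd covariate, 420 without the low-Hoxd libraries, 299 with DESeq2, 485 with voom and 10 with only the compared groups. For the difference of fiber effects, 1 became 6 without the low-Hoxd libraries and 20 with DESeq2. The cause was not tested.

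Averaged over both diets, the count of 1 for oligofructose became 0 without the name set term, 0 with the S libraries, 13 with the Hoxd covariate, 2 without the low-Hoxd libraries, 59 with DESeq2 and 7 with voom. Averaged over both fibers, 626 for diet became 384 without the name set term, 1449 with the Hoxd covariate, 2550 without the low-Hoxd libraries, 1121 with DESeq2 and 1969 with voom. With 1 library left out, the counts ranged over 0 to 59, 1 to 3, 0 to 2, 19 to 363, 12 to 309 and 1 to 2 for the 6 comparisons in the order above, 0 to 19 for the fiber average and 284 to 957 for the diet average. The cause was not tested.

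Lists called went from 15 to 0 with an estimated correlation, 2 by directional fry, 3 by mixed fry and 5 with the smooth muscle covariate between obese and lean mice on cellulose. For oligofructose in obese mice they went from 18 to 0, 2 and 2 in the first 3 of these settings. In lean mice they went from 17 to 0, 1 and 0, with 10 for the S libraries and 9 to 18 with 1 library left out. They went from 13 to 3 and 4 by estimated correlation and directional fry between obese and lean mice on oligofructose, from 13 to 4 and 8 between obese oligofructose and lean cellulose, and from 11 to 0 and 0, with 1 by mixed fry, for the difference of fiber effects. The return toward lean went from 84.2% to 57.9% with the obese cellulose libraries split, to 62.3% without the low-Hoxd libraries and to between 60% and 100% with 1 library left out. These ends rest on few genes, 3 of 5 without lean cellulose replicate 2 and 1 of 1 without obese cellulose replicate 1. Without obese cellulose replicate 3 it had no value, since 0 genes changed. The cause was not tested.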

Other observations

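Averaged over both fibers, the obese diet raised Arg2, Creb3l3, Cxcl1, Tnf and Egln3 and lowered Hmga1. This average, and the one over both diets, was added after the 6 comparisons had been seen. Arg2 rose by 1.65 (SE 0.166), Creb3l3 by 2.13 (SE 0.253), Cxcl1 by 2.28 (SE 0.322), Tnf by 1.45 (SE 0.219) and Egln3, an oxygen-sensing hydroxylase, by 1.03 (SE 0.118) on the log2 scale, and Hmga1 fell by 0.55 (SE 0.0611). Cxcl1 rests on few counts in lean mice, with means of 0.45 CPM on cellulose and 0.261 on oligofructose. In all, 626 genes changed, 344 higher and 282 lower, and 3122 had an unadjusted p under 0.05. Of the fatty acid oxidation and ketogenesis list 12 of 33 rose, with 17 higher and 1 lower when adjusted over the list alone (camera adjusted p = 3e-16, adjusted p = 0.028 with an estimated correlation). Of the stem cell list 3 of 16 fell, Axin2, Rgmb and Lgr5, with 10 lower when adjusted over the list alone (adjusted p = 0.0216 with an estimated correlation). Of the circadian clock list, Dbp, Tef, Nr1d1 and Nr1d2 rose and Arntl and Npas2 fell, 6 of 20. Adjusted over the list alone, 7 were higher and 2 lower. The list was not called (camera adjusted p = 0.214), but camera asks for a shift in 1 direction and can miss members that move both ways. Between obese and lean mice on oligofructose, fry in either direction called the list (adjusted p = 0.00938). Of the inflammatory list 5 of 21 rose, and 6 when adjusted over the list alone (camera adjusted p = 2.83e-05, adjusted p = 0.236 with an estimated correlation). Other lists moved with it, with medians of 0.437 for T and natural killer cells (camera adjusted p = 0.000141), 0.356 for MHC class II antigen presentation (0.000625), 0.519 for B and plasma cells (0.00632) and -0.434 for heat shock (0.000588). With an estimated correlation their adjusted p was 0.671 to 0.733, and none of their members passed over all genes by edgeR. The labels give no time of collection.

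Averaged over both diets, oligofructose was accompanied by higher Ceacam10, from 35.9 ± 7.05 to 54.2 ± 5.49 CPM in lean and from 37.3 ± 8.16 to 64.8 ± 16.4 in obese mice (log2 fold change 0.69, SE 0.094, adjusted p = 0.032). It was the 1 gene that changed, and 1396 had an unadjusted p under 0.05. The count was 0 without the name set term and with the S libraries alone, and 0 to 19 with 1 library left out. In the B and plasma cell list 0 of 19 members passed by edgeR and 6 were higher when adjusted over the list alone (median 0.41, camera adjusted p = 3.94e-16, adjusted p = 0.143 with an estimated correlation). Lists of other cells moved as well, with medians of 0.25 for MHC class II antigen presentation (camera adjusted p = 5.75e-05), 0.244 for T and natural killer cells (0.000182), 0.237 for enteric neurons and glia (7.5e-07), 0.184 for proliferation (8e-05) and -0.13 for fibroblasts and extracellular matrix (4.03e-05). With an estimated correlation their adjusted p was 0.408 to 0.517. The antimicrobial and epithelial defence list had a median of 0.365 (camera adjusted p = 2.24e-07, adjusted p = 0.143 with an estimated correlation). The immediate early list had one of 0.29 (camera adjusted p = 3.75e-07, adjusted p = 0.336 with an estimated correlation). Igha, the heavy chain of IgA, was at 864 ± 233 and 1500 ± 177 CPM in lean and 675 ± 248 and 1350 ± 255 in obese mice, on cellulose and oligofructose, and did not pass (adjusted p = 0.202). Mast cell and eosinophil genes had a median of -0.76, with 0 of 9 past the threshold and 4 lower when adjusted over the list alone (camera adjusted p = 0.000629, adjusted p = 0.0929 with an estimated correlation).

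Each count of changed genes was set beside the counts from other splits of the same libraries. The splits over all libraries were written down before their values were computed, and those that keep 1 d_colon library on each side, as the name set term of the fit asks, were added only after the results were seen. For obese against lean on cellulose 1 of 35 splits changed as many genes (real 19, highest other 0), for oligofructose in obese mice 1 of 35 (real 2, highest other 0) and for obese against lean on oligofructose 1 of 35 (real 168, highest other 4). For these 3 comparisons the share of splits falls under 0.05 only where splits with uneven name sets count as equal to the real one. The 20 splits that keep the name sets even are too few for a share under 0.05, with the same real values and highest others and 1 split as large in each comparison. For oligofructose in lean mice 3 of 35 changed as many (real 1, highest other 245), and 3 of the 20. For obese oligofructose against lean cellulose 3 of 35 did (real 55, highest other 1442), and 2 of the 20. Chance cannot be excluded for either, and in both the highest other split put every low-Hoxd library on 1 side, which points to a structure of the libraries.

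For the difference of fiber effects 2 of 100 drawn splits changed as many genes (real 1, highest other 1), and 9 of 100 among those that keep the name sets even (highest other 599), so chance cannot be excluded for this count. For the fiber average 3 of 100 did (real 1, highest other 10), and 6 of 100 with even name sets (highest other 85), so chance cannot be excluded there either. For the diet average 1 of 100 did, the real one, in both draws (real 626, highest other 163 and 555). No other drawn split reached the real count, but the highest one with even name sets, at 555, came near it. The splits also treat libraries as exchangeable, and the labels do not say that each came from a separate animal.

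Transcripts of adipocytes varied between libraries of a group. Lep was at 2.47 ± 1.91 CPM in lean cellulose, 1.32 ± 0.99 in lean oligofructose, 20.4 ± 29.8 in obese cellulose (0.921 to 64.1) and 18.1 ± 26.9 in obese oligofructose (0.479 to 58.2). In obese cellulose replicates 1 to 4, Lep was at 64.1, 14.6, 1.82 and 0.921 CPM and Itgad, named above, at 10.9, 4.42, 1.49 and 0.838. Angptl4 was at 31.5, 5.32, 8.12 and 4.66 CPM and Adipoq at 55.8, 4.85, 7.42 and 1.23 in obese oligofructose replicates 1 to 4. In lean oligofructose replicates 1 to 4 Angptl4 was at 5.65, 3.94, 3.1 and 3.03 CPM, highest where Adipoq was lowest, at 0.112. Dgat2 was at 102, 75.6, 63 and 50.4 CPM in obese cellulose replicates 1 to 4, in the order of Adipoq at 38.6, 13.1, 3.31 and 1.93. In lean oligofructose replicates 1 to 4 Dgat2 was at 54, 30.1, 32.5 and 30.3 CPM beside Adipoq at 0.112, 10.6, 16.5 and 4.28. The adipocyte list itself was not called between obese and lean mice, with a median of 0.05 on cellulose (camera adjusted p = 0.547) and 0.25 on oligofructose (camera adjusted p = 0.168, median -0.247 to 0.506 with 1 library left out), beside log2 fold changes of 2.44 (SE 0.41) for Angptl4 on cellulose and of 5.24 (SE 1.05) for Itgad and 1.252 (SE 0.271) for Dgat2 on oligofructose. Without the 4 low-Hoxd libraries the list was called lower on oligofructose (median -0.485, camera adjusted p = 0.00258), and with the S libraries alone it was called lower on both (-0.256 on cellulose, 0.0359, and -0.339 on oligofructose, 0.0115). Whether these genes differ within adipose tissue in the piece stays open. Adipoq was at 12.1 ± 6.8, 7.88 ± 7.2, 14.2 ± 17 and 17.3 ± 25.8 CPM in the same order.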
